A study of Mus musculus with 18 samples.

How the data were processed

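RNA sequencing was analysed for 18 libraries of mpkCCD cells, 9 control and 9 treated with dDAVP, grouped by the names in the labels. Per the labels' protocols, 20 ng of RNA was used as input and single-end reads of 50 bp were sequenced. The protocols describe both a low-input amplification kit and a single-cell style protocol without saying which library had which. Per the submitters' processing notes, STAR 2.4.0.1, SAMtools and HTSeq were used with mouse build mm10; the annotation release and the strand setting of the counting are not stated, so counts of overlapping antisense genes are uncertain. The deposited count table holds raw counts per gene symbol and library, as whole numbers. The deposited FPKM table holds FPKM values that the authors scaled by a length fixed for each gene and by each library's counted reads: count divided by FPKM varied by a median of 0.019% once scaled by library totals.

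There were 24111 genes with counts and 24076 with FPKM values, of which 24071 were in both, and 15481 genes had a count in any library. Spreadsheet software had turned 27 gene symbols into dates; 22 were restored by matching counts to FPKM values (at most 0.5% variation) and the other 5 had 0 counts throughout. Gene positions came from GENCODE M21 on GRCm38, in which 98.3% of symbols matched a single gene. Duplicated libraries were checked by chi-square per degree of freedom between libraries of a group, of which the lowest was 71.6. Library totals ranged from 22.2 to 105.9 M counts. The floor of 3 counts covers counting error only, since reads without molecular identifiers are not independent molecules. Paralogs with near-identical sequence (the Sprr2 genes, Aldh1a7 with Aldh1a1, the repeated Rn45s and ribosomal protein pseudogenes) can share reads.

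The planned comparison used edgeR 4.0.16 quasi-likelihood tests on all 18 libraries without covariates, with TMM normalization, filterByExpr (10121 genes kept) and Benjamini-Hochberg adjusted p under 0.05, two-sided. Normalised CPM are CPM computed from the TMM-scaled library total, and log2 CPM were shown with an offset of 1 CPM. Single genes and library measures were compared by two-sided exact permutation tests. Gene lists, 27 in all and written from textbook knowledge, were tested by camera in limma 3.58.1 with a preset correlation of 0.01, with an estimated correlation, and by fry, where at least 3 members passed the filter. Other tools were DESeq2 1.42.0, limma voom with and without sample quality weights, sva 3.50.0, R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The groups, the tests, the lists, the rule for naming genes and a set of other settings were fixed before the data were examined. These settings were other normalizations, other count tests, no or a strict filter (1 CPM in 9 libraries), robust quasi-likelihood, the replicate number as a block, surrogate variables, the log10 library total, each library or replicate number left out, and the FPKM values. The set term, the fits within sets of replicate numbers, their interaction with treatment and the alternatives of these fits were chosen after seeing the data.

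The rule named 7 genes in any case (Aqp2, Aqp3, Aqp4, Avpr2, Scnn1a, Scnn1b and Scnn1g). It further named, among called genes with a mean of at least 1 CPM, the 10 with the largest rise and the 10 with the largest fall, leaving out predicted genes, RIKEN clones and small RNAs. In each list it named up to 3 called members with the smallest adjusted p, or else up to 2 with the highest mean, as values only. Genes named outside this rule are said to be chosen after their values were seen. The text gives part of the genes that the rule names, with few of the most abundant list members, and 1 gene is not reported here.

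The labels number the libraries 1 to 9 in both groups without saying whether equal numbers were cultured or prepared together. The pairing check correlated deviations from the group means between libraries of the same number, which gave r of 0.88, 0.78, 0.81, 0.69, 0.53, 0.47, 0.33, 0.51 and 0.40 for numbers 1 to 9, across genes, which are not independent replicates. In these correlations a control library's own number was its best match among dDAVP libraries in 3 of 9 cases. After removal of the set means, the correlations of the same number lay between -0.60 and 0.31, so the values above came mostly from the sets. The replicate number was therefore fitted as a block only as an alternative. Nothing says that replicates are separate cultures, so the p-values measure spread between samples.

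The fits were tested on simulated data, 3 runs with 200 changed genes each. Counts were drawn gene by gene from the means, spread and library sizes of each set, without structure shared across genes within a set. The rates below therefore need not hold for the real libraries. Without covariates edgeR recovered 0% of 2-fold, 10.4% of 4-fold and 71.7% of 16-fold changes. Recovery of 4-fold changes was 63.7% with the replicate block, 76.1% with the set term, 44.3% with limma voom and sample quality weights, 88.6% with weights and the set term, and 43.3% with DESeq2. Within sets it was 81.1% in replicates 1 to 3, 13.4% in replicates 4 to 6 and 1.5% in replicates 7 to 9. False calls per run were 0 without covariates, 1.3 with the set term, and 11.7 both in replicates 1 to 3 and with weights and the set term. RNA polymerase 2 ChIP-seq, mentioned in the series' description, was not analysed here.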

Results

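RNA was measured by sequencing in mpkCCD cells, an immortalised mouse line with features of the principal cells of the kidney collecting duct, the cells in which vasopressin sets water reabsorption. Per the labels' protocols, cells kept without serum for 24 h were then left untreated (control) or given 0.1 nM dDAVP (desmopressin, an analogue of vasopressin that acts on its V2 receptor) for another 24 h. There were 9 control and 9 dDAVP libraries, numbered 1 to 9 in each group. The counted reads of control libraries 1 to 9 came to 23.8, 23.4, 27.7, 27.6, 33.8, 36.5, 41.4, 78.6 and 61.5 M. Those of dDAVP libraries 1 to 9 came to 22.2, 25.6, 25.5, 33.8, 37.8, 27.3, 105.9, 66.5 and 72.8 M. Mean log10 totals did not differ detectably between the groups (7.56 ± 0.18 in control, 7.60 ± 0.24 in dDAVP, SD, n = 9 each; two-sided exact permutation p = 0.675). By counting error alone, a gene with 0 counts in a library could have held up to 3 counts. That is 0.028 to 0.135 CPM (counts scaled to library size), depending on the library. In dDAVP libraries 4 to 6, of 8488 genes with at least 100 counts in a library, 444 had 0 counts in another. The same held for 123 of 8834 genes in control libraries 4 to 6. In libraries 7 to 9 it held for 406 of 10403 in control and 425 of 10929 with dDAVP. In libraries 1 to 3 it held for 0 of 5759 in control and 7 of 5785 with dDAVP. A count of 0 in libraries 4 to 9 therefore need not mean expression below these CPM values.

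The comparison of dDAVP with control asks which transcripts of these cells differ after activation of the V2 receptor. Aqp2, which encodes the water channel aquaporin-2 of the principal cell (chromosome 15, 99579055 to 99584547, mm10), averaged 54.7 ± 74.7 normalised CPM in control and 1276 ± 1069 normalised CPM in dDAVP libraries (SD, n = 9 each). Its log2 fold change was 4.54 (SE 0.84), and it was higher with dDAVP in 8 of the 9 replicate numbers. Equal numbers are not known to be pairs, so this and later counts of numbers can depend on the matching and are descriptive only. Cited1, a transcriptional coactivator (chromosome X, 102247381 to 102252181), averaged 0.873 ± 0.849 CPM in control and 45.4 ± 46.1 CPM with dDAVP, a log2 fold change of 5.71 (SE 1.11), and was higher with dDAVP in 9 of 9 numbers. B3gnt7, a glycosyltransferase that extends sugar chains of glycoproteins (chromosome 1, 86302832 to 86307305), averaged 10.5 ± 11.8 CPM in control and 62.4 ± 52.4 CPM with dDAVP, a log2 fold change of 2.57 (SE 0.77), and was also higher in 9 of 9 numbers.

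In the planned fit of all 18 libraries without covariates, edgeR called 0 of 10121 genes at an adjusted p under 0.05, and 218 genes had an unadjusted p under 0.05. Aqp2 and Cited1 had the lowest edgeR adjusted p, 0.203 each. The single-gene test planned for Aqp2, a two-sided exact permutation test of its log2 CPM over 48620 regroupings, gave p = 0.000165 (0.00072 after Benjamini-Hochberg adjustment over the 14 genes so tested). Beside the 7 genes fixed in advance, those 14 hold genes called with the set term below. The latter were picked on these same libraries, which can lower the adjusted p. Other tools and covariates fixed in advance called few genes, each of them higher with dDAVP: 6 with DESeq2, 1 with limma voom, 11 with limma voom and sample quality weights, 7 with surrogate variables, 2 with the deposited FPKM values and 1 with the replicate number as a block. The gene called with the block was Cited1 (log2 fold change 5.98, SE 0.81, edgeR adjusted p = 0.00855). The 6 genes of DESeq2 were Aqp2, Cited1, Bcat1, Eya2, Efnb3 and Eif2s3y, the last pair chosen after their values were seen. Neither of that pair was among the 11 genes called with sample quality weights. The weights of libraries 1 to 3 lay between 2.19 and 4.84 and those of the others between 0.29 and 0.96, so the weighted fit rests mostly on libraries 1 to 3. Its 11 genes included Aqp2 (log2 fold change 5.91), Cited1 (7.61), Car15 (4.54), B3gnt7 (4.12), the water channel gene Aqp5 (3.60), C3 (3.35), Arhgef3 (2.75), Bcat1 (2.43), Eya2 (1.79) and Cdk18 (1.22). Without weights, in edgeR, the log2 fold changes of Car15 and Aqp5 were 2.13 (SE 0.93) and 1.36 (SE 0.89), and that of Aqp5 was 2.94 without replicate 8. Without control 9, edgeR called 1 gene, Aqp2. The count of 11 became 4 without control 1, 2 or 3, 5 without dDAVP 1, 1 without dDAVP 2 or dDAVP 3, and between 17 and 33 without any other single library.

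The libraries fell into 3 sets by replicate number (1 to 3, 4 to 6 and 7 to 9) rather than by treatment. The first principal component held 37.9% of the variance of log2 CPM, and the sets accounted for 84.3% of it against 0% for treatment. For the second component (31.8% of the variance) these shares were 95.6% and 0.4%. The median correlation across genes, which are not independent replicates, was 0.86 between libraries of the same set and group, 0.84 between libraries of the same set and the other group, and 0.59 between libraries of the same group in other sets. Transcripts of all ribosomal protein genes, taken by their symbols, together took 20.8 to 28.8% of the counts in libraries 1 to 3, 0.86 to 10.2% in libraries 4 to 6 and 10.2 to 16.1% in libraries 7 to 9. The ribosomal RNA precursor Rn45s took at most 0.007% in libraries 1 to 6 and 0.213 to 3.04% in libraries 7 to 9. Library dDAVP 6 stood apart, with 10282 genes detected and 0.86% ribosomal protein transcripts.

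**Figure D1:**
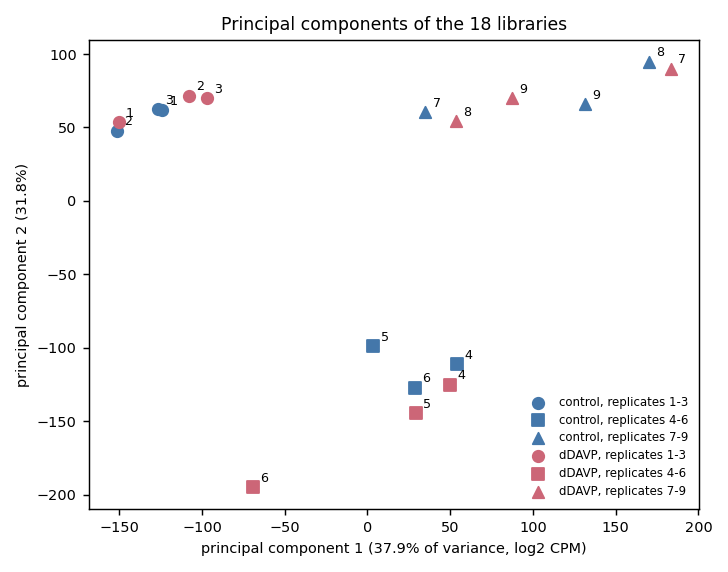
Principal components of log2 CPM over the 10121 genes tested, 1 point per library with its replicate number, colour for treatment and symbol for the set of replicate numbers. The axes give the first (37.9% of the variance) and the second component (31.8%), and the points gather by set, with control and dDAVP libraries side by side.

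With the set as a term, a fit chosen after seeing the data, 8 genes rose with dDAVP and 0 fell by edgeR, with 610 of 10121 genes at an unadjusted p under 0.05. Cited1 (log2 fold change 5.19, SE 0.77), Aqp2 (4.63, SE 0.72) and B3gnt7 (3.16, SE 0.49) each had an edgeR adjusted p of 0.00504. Arhgef3, an exchange factor that activates small GTPases (chromosome 14, 27114899 to 27403911), rose by a log2 fold change of 2.44 (SE 0.42), from 2.34 ± 2.18 to 12.2 ± 9.52 CPM. Complement component C3 (chromosome 17, 57203970 to 57228136) rose by 2.31 (SE 0.39). It averaged 50.8 CPM in control and 483 CPM with dDAVP in libraries 1 to 3, 19.5 and 59.4 CPM in libraries 4 to 6, and 4.72 and 20.0 CPM in libraries 7 to 9. The metabolic enzymes Idh1, cytosolic isocitrate dehydrogenase (chromosome 1, 65158616 to 65186500), and Bcat1, cytosolic branched-chain aminotransferase (chromosome 6, 144993835 to 145076184), rose by 2.26 (SE 0.38) and 2.01 (SE 0.37). Eya2, a transcriptional coactivator with phosphatase activity (chromosome 2, 165595032 to 165771727), rose by 1.76 (SE 0.34), from 3.27 ± 1.41 to 11.4 ± 5.01 CPM. Each of the 8 genes was higher with dDAVP in 9 of 9 replicate numbers, except Aqp2 and Arhgef3 in 8. Exact permutation within the sets, over 8000 regroupings and also chosen after seeing the data, gave p = 0.00075 for Aqp2, 0.0005 for Arhgef3 and 0.00025, the smallest it can give, for each of the other 6. These 8 genes were selected on the same libraries, so their values here are no independent evidence. Over all 48620 regroupings, which ignore the sets, the exact permutation p was 0.17 for Idh1 (0.265 adjusted over the 14 genes) and 0.0229 for C3 (0.0457 adjusted). It was at most 0.00239 for each of the other 6. The count of 8 fell to 4 without dDAVP 8, to 0 without libraries 1 to 3 (484 genes at an unadjusted p under 0.05) and to 0 without libraries 4 to 6 (699 such genes). It was 40 with DESeq2 (31 higher and 9 lower) and 118 with weighted limma voom (91 higher and 27 lower). DESeq2 called 7 of the 8 genes, and gave no p-value for Aqp2 (log2 fold change 4.54).

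**Figure D2:**
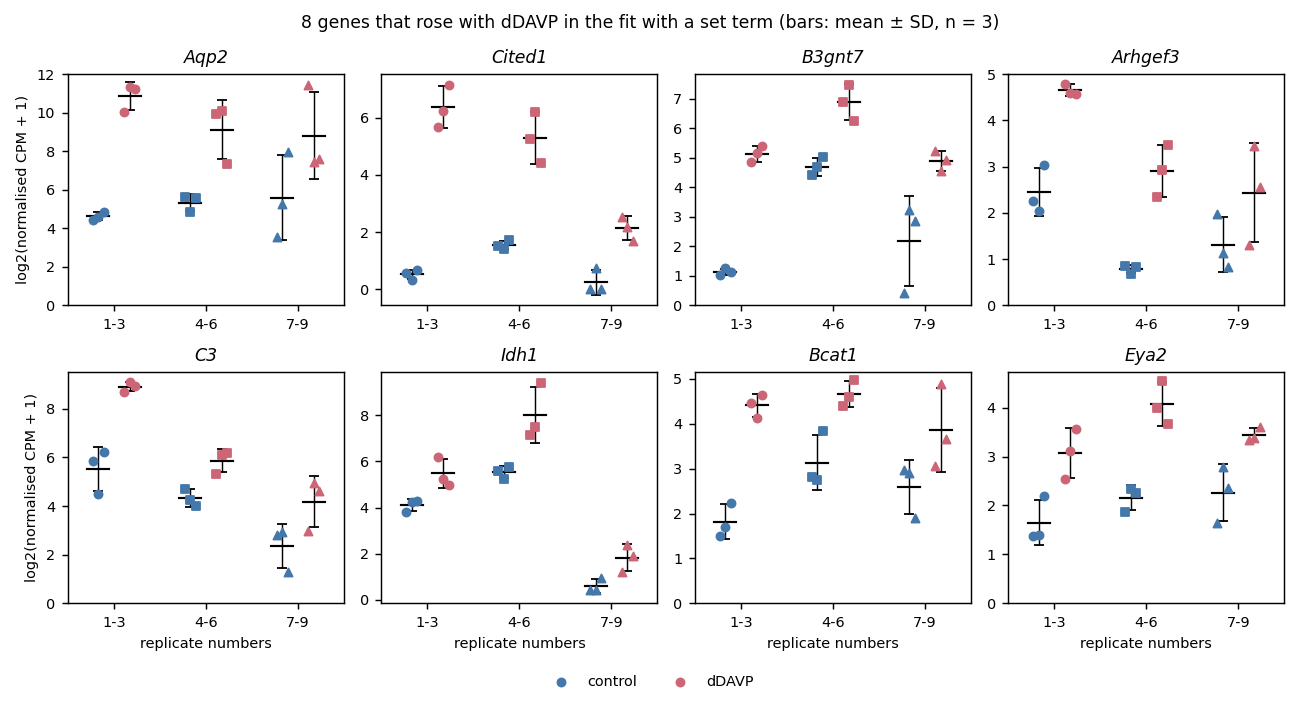
Log2(normalised CPM + 1) of the 8 genes called with the set term, by replicate numbers on the horizontal axis, 1 point per library (blue control, red dDAVP); bars give the mean and SD of 3 libraries. Aqp2 in libraries 1 to 3 lies near 24 CPM in control and near 2036 CPM with dDAVP, while in libraries 7 to 9 control and dDAVP values overlap.

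Set by set, Aqp2 ranged from 20.5 to 27.9 CPM in control and from 1050 to 2636 CPM with dDAVP in libraries 1 to 3, and from 27.3 to 48.2 and from 162 to 1097 CPM in libraries 4 to 6. In libraries 7 to 9 it was 10.8, 37.2 and 251 CPM in control and 2756, 174 and 192 CPM with dDAVP, so 1 library in each group lay far above the others. Cited1 ranged from 0.264 to 0.586, 1.69 to 2.28 and 0 to 0.693 CPM in control, and from 50.7 to 142, 20.3 to 72.9 and 2.25 to 4.79 CPM with dDAVP, in the same order of sets. Spread between libraries also differed by set: the common biological coefficient of variation was 0.292, 0.744 and 0.882 in the 3 sets, and 1.06 over all libraries without a set term. Among the libraries numbered 1 to 3 alone (n = 3 per group, chosen after seeing the data), edgeR called 41 of 8991 genes, 34 higher and 7 lower with dDAVP. Of these, 36 are also among the 118 genes of the weighted fit with the set term. That fit includes the same libraries, so the overlap is no independent evidence. With the replicate number as a block the count in libraries 1 to 3 was 101 (65 higher, 36 lower), and with DESeq2 it was 113. It was 14, 13 and 15 without control 1, 2 and 3, 24 without dDAVP 2 and 774 without dDAVP 1. In libraries 4 to 6 and in libraries 7 to 9 edgeR called 0 genes, with 479 of 10387 and 590 of 11367 genes at an unadjusted p under 0.05. With the set term in libraries 4 to 9 it called 0 of 10761 (484 at an unadjusted p under 0.05). No other tool was run on these subsets.

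The 10 genes with the largest rise in libraries 1 to 3 were Cited1 (log2 fold change 7.52), Aqp2 (6.32, SE 0.36), Car15 (5.06), B3gnt7 (4.77), Sprr2g (4.59), Spink8 (4.49), Arg2 (4.30), Aqp5 (4.09), Scg5 (4.09) and Smpdl3a (3.97). They include a membrane-bound carbonic anhydrase (Car15), a mitochondrial arginase (Arg2), a Kazal-type protease inhibitor (Spink8) and a chaperone of prohormone processing (Scg5). Sprr2g belongs to a family of near-identical genes, so its counts are uncertain. Crem, a cAMP-responsive transcription factor, rose by 2.36 (SE 0.43), and the carbonic anhydrase gene Car12 rose by 2.99 (SE 0.36). In libraries 7 to 9 the log2 fold changes of Crem and Car12 were negative, -1.12 (SE 1.12) and -1.17 (SE 1.38). The named genes that fell in libraries 1 to 3 included the small GTPase genes Rasl11a (-2.82) and Rasl11b (-1.82) and the stress-response factor Atf3 (-2.51). The others were the extracellular matrix genes Fras1 (-1.85) and Frem2 (-1.61), and carboxypeptidase E (Cpe, -1.72). Libraries 4 to 9 had no part in choosing these genes: there, with the set term, 30 of the 32 measured genes that rose had a positive log2 fold change (median 0.95, limma fry adjusted p = 0.0064). Of the 7 that fell, 6 had a negative one (median -0.58), which did not pass the test (limma fry adjusted p = 0.0614). In libraries 4 to 6 the counts were 28 of 32 (fry adjusted p = 0.00675) and 7 of 7 (fry adjusted p = 0.00668). In libraries 7 to 9 they were 24 of 32 (fry adjusted p = 0.136) and 5 of 7 (fry adjusted p = 0.463), with adjustment over these 6 tests. A test of the difference itself, an interaction of set and treatment in edgeR, called 0 of 10121 genes (671 at an unadjusted p under 0.05; no other tool was run).

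**Figure D3:**
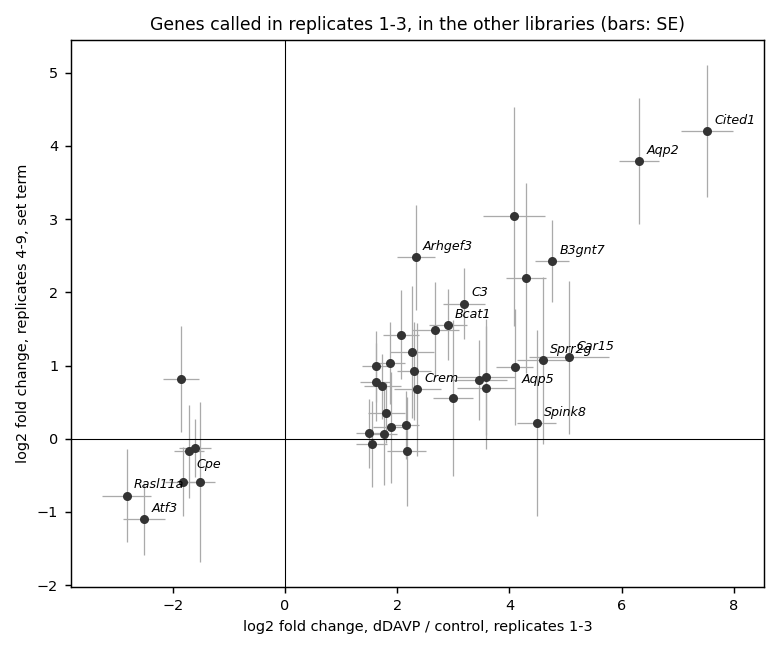
Each point is a gene called in replicates 1 to 3 and measured in the other libraries, with its log2 fold change (dDAVP over control) in replicates 1 to 3 on the horizontal axis and in replicates 4 to 9, with the set term, on the vertical axis; bars are SE. Of 32 genes that rose in replicates 1 to 3, 30 lie above 0 on the vertical axis, with Cited1 (4.21) and Aqp2 (3.80) the highest.

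The other genes of water and sodium transport fixed for report did not pass the test in the fit without covariates. Avpr2, the V2 receptor, averaged 33.9 ± 12.9 CPM in control and 38.2 ± 15.5 CPM with dDAVP. The epithelial sodium channel subunits averaged 37.2 ± 29.0 and 37.0 ± 37.2 CPM for Scnn1a, 4.31 ± 4.85 and 1.35 ± 1.47 CPM for Scnn1b, and 1.21 ± 1.68 and 1.18 ± 2.01 CPM for Scnn1g. The water channel genes Aqp3 (0.479 ± 0.573 and 1.22 ± 2.06 CPM) and Aqp4 (3 counts over the 18 libraries) fell below the filter. Two-sided exact permutation p-values of these 6 genes lay between 0.161 (Scnn1b) and 1 (Aqp4), and the fold of Scnn1b could not be told from 0 (log2 -1.67, SE 0.93).

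Of 27 gene lists, 26 had enough members to test. In the fit without covariates, camera called 1 list, the ribosomal protein genes: 37 of 48 had a negative log2 fold change (median -0.14), with 0 called singly and a camera adjusted p of 0.00754. The call is lost with an estimated correlation (camera adjusted p = 0.863 with an estimated correlation), and the median was of the size by which another scaling moves all genes (0.20 on the log2 scale with library totals only). With the set term 46 of 48 were negative (median -0.35, camera adjusted p = 5.51e-06, and adjusted p = 0.517 with an estimated correlation). A list of mitochondrial, nuclear non-coding, histone and ribosomal precursor transcripts was fixed as a sign of RNA fractionation. Only 6 of its 23 members were tested, the most abundant being Rn45s (2787 CPM) and Neat1 (545 CPM). With the set term this list was also lower (5 of 6 negative, camera adjusted p = 0.0489, and adjusted p = 0.264 with an estimated correlation). With so few members tested, the call is not read as one about mitochondrial transcripts. Many ribosomal protein genes have near-identical pseudogenes that can share their reads. The 48 ribosomal protein genes of the list, fewer than all those taken by symbol, took 19.1% of counts in control and 19.0% with dDAVP in libraries 1 to 3, 5.36% and 2.76% in libraries 4 to 6, which include dDAVP 6, and 10.6% and 10.1% in libraries 7 to 9. No member of any list passed over all genes in the fit without covariates; adjusted over the list alone, Aqp2 rose among principal cell genes and C3 among inflammatory genes, and no other list had such a gene. With the set term, adjusted over the list alone, Aqp2, Akap12, Stat3, Bpnt1 and C3 rose and Atf3, Jun and Oasl2 fell.

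In libraries 1 to 3, camera called 4 lists. Principal cell genes were higher (10 of 15 positive, median 0.26, camera adjusted p = 0.0266, and adjusted p = 0.586 with an estimated correlation). Adjusted over the list alone 5 rose (Aqp2, Atp1b1, Fxyd4, Kcnj16 and Tmem45b) and 1 fell (Tfcp2l1). Intercalated cell genes were higher (7 of 8 positive, median 1.81, camera adjusted p = 0.00025, and adjusted p = 0.586 with an estimated correlation). Adjusted over the list alone 5 rose, the carbonic anhydrases Car12 and Car15, the proton pump subunits Atp6v0a4 and Atp6v1b1 and the channel Aqp6, and the Notch ligand Jag1 fell. Cell cycle genes (32 of 41 negative, median -0.24, camera adjusted p = 0.00121) and interferon response genes (17 of 22 negative, median -0.33, camera adjusted p = 0.00521) were lower. These calls too are lost (adjusted p = 0.586 with an estimated correlation for each). Adjusted over the list alone 0 and 4 members fell (Ifit2, Oas2, Oasl2 and Rtp4). Directional fry called 0 lists in libraries 1 to 3, against 7 by fry for change in either direction. Among targets of cAMP and CREB, 15 of 22 were positive and camera made no call. Adjusted over the list alone Crem, Id3 and Rgs2 rose while Atf3 and Jun fell. Among other transporters Aqp5, Slc3a2 and Trpv4 rose adjusted over the list alone. In the remaining lists C3, Btc, Elf3 and Krt19 rose, and Calm2, Cdh1, Myl12a, Lrp2 and Podxl fell, adjusted over the list alone. Those of these members that passed over the list alone but not over all genes were chosen after their values were seen.

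The other lists gave no camera call in the fit without covariates (adjusted p of 0.143 or more). Members with a positive log2 fold change there numbered 10 of 17 for principal cell genes, 8 of 10 for intercalated cell genes, 14 of 17 for other transporters, 13 of 30 for cAMP and CREB targets, 19 of 36 for cAMP signalling, 22 of 44 for aquaporin-2 trafficking, 31 of 58 for candidate transcription factors, 9 of 12 for osmotic response genes and 12 of 21 for steroid response genes. They numbered 9 of 22 for tight junction genes, 15 of 28 for epithelial genes, 10 of 17 for mesenchymal genes, 15 of 35 for actin and serum response genes, 24 of 41 for cell cycle genes, 7 of 21 for p53 targets, 15 of 32 for endoplasmic reticulum stress genes, 23 of 31 for sterol synthesis genes and 16 of 28 for glycolysis and hypoxia genes. For respiratory chain genes they numbered 22 of 38, for inflammatory genes 6 of 12, for interferon response genes 7 of 23, for growth factor genes 16 of 23, for Wnt and Notch genes 10 of 19, for other nephron segments 1 of 3 and for the fractionation list 1 of 6. Markers of endothelial, immune, fibroblast and blood cells took 0.002% of the counts, too few to test. Camera's direction went against the median for cAMP and CREB targets, trafficking genes, candidate transcription factors, mesenchymal, respiratory chain and Wnt and Notch genes, and against the mean for endoplasmic reticulum stress genes. Among the most abundant members, given as values only and picked from the rule's list after their values were seen, Gnas averaged 1210 CPM, Atp1b1 648 CPM, Slc3a2 388 CPM, Jund 286 CPM and Krt18 4612 CPM over the 18 libraries.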

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

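The tests chosen after their result was seen were the count of splits for the fit without covariates, the tests of spread and of no effect in replicates 4 to 9, and the test of swapped labels. Of 110 groups of 9 libraries checked, 8 held a library far from the others (a gap to the next library above Dixon's 95% critical value), where chance gives about 1 in 20 groups, or 5.5. In log2(CPM + 1), Aqp2 in control 9 was 7.98 and the next control 5.62. Control 8 was highest for Aqp5 (5.39, next 2.61) and Scg5 (1.53, next 0.594). Aldh1a7 stood out in control 4 (1.61, next 0.239) and in dDAVP 6 (3.80, next 1.16). Aqp4 was above 0 in single libraries, control 5 (0.068) and dDAVP 3 (0.079). The Rn45s share of dDAVP 7 was 0.847% and the next 0.268%.

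The libraries fell into sets by replicate number. With depth equalised by thinning to the smallest total, 64.8% of the variance lay between sets, against 63.2% before, which argues against sequencing depth as the whole cause. Removing each library's trend with gene length left 62.4%, and removing its trend with GC content left 61.3%, so neither trend was the whole cause. A difference between library protocols may remain as a source, since the labels' protocols describe more than one. They do not say which library had which. Libraries 4 to 6 also differed in list shares, picked after their values were seen. Mesenchymal genes took 1.4% of counts in control and 1.7% with dDAVP there, against 0.023 to 0.0704% in the other sets. Epithelial genes took 0.33% and 0.27% there, against 1.6 to 2.08% in the other sets. Single abundant genes can carry such shares, as Skil among mesenchymal genes (8235 CPM on average). A difference in the cells also stays open, and no biological explanation was tested.

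Genes were called in replicates 1 to 3 (41) and by edgeR in neither of the other sets (0 each, with 479 and 590 genes at an unadjusted p under 0.05; no other tool was run there). A candidate explanation is larger spread: the common coefficient of variation was at least 2.55 times that of replicates 1 to 3. An absence of any effect in replicates 4 to 9 is argued against by the genes that rose in replicates 1 to 3 (30 of 32 positive, limma fry adjusted p = 0.0064). Whether the effect also differs in size stays open. The interaction in edgeR called 0 genes (671 at an unadjusted p under 0.05), and no other tool was run for it. Among the genes called with the set term, its unadjusted p was 0.0405 for Cited1 and 0.0304 for B3gnt7. For the others of these genes it lay between 0.108 (Aqp2) and 0.537 (Eya2).

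Replicates 7 to 9 divided across the labels: control 7, dDAVP 8 and dDAVP 9 against control 8, control 9 and dDAVP 7 gave 1050 genes, and Avpi1, chosen after its values were seen, was 487, 711 and 647 CPM in the latter 3 and 71.3, 31.2 and 57.3 CPM in the former. After thinning to the smallest total 1055 genes were called, which argues against depth as the whole cause. Had control 7 and dDAVP 7 been swapped, the genes that rose most in replicates 1 to 3 would be lower in dDAVP 7, yet 8 of 10 were higher there. Those libraries lie on opposite sides of the division, so a gene could be higher in dDAVP 7 through its side. The count therefore cannot decide on this swap. An exchange of both 8 and 9 between the groups would undo the division as well. That exchange was not tested, and genes that rose in replicates 1 to 3 point both ways. As labelled, in replicates 7 to 9 Cited1 had a log2 fold change of 3.97 (SE 1.77). Avpi1, which rose by 1.76 (SE 0.23) in replicates 1 to 3, had -0.83 (SE 1.15). Of 32 such genes 24 were positive, which did not pass (limma fry adjusted p = 0.136). The labels of these libraries therefore stay unchecked. A difference in handling or in the cells may lie behind this division, and no biological explanation was tested.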

How the results depend on the processing

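The fits with a set term, those within sets and the block with sample quality weights were chosen after the data were seen, and so were all alternatives to the counts of 8, 11 and 41 genes; the other alternatives were planned. Over 76 gene results and 1894 alternatives other than leaving out libraries, 1762 counted as unchanged, 98 gained a call, 25 reversed and 9 moved. For genes given as values only, a change of sign was not counted as a reversal, so directions may differ among the 1762. Without dDAVP 6, for example, the log2 fold change of Actb went from 0.83 to -0.20 and counted as unchanged. Where no cause is given, the cause was not tested.

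The Aqp2 fold change (log2) stayed positive and passed the threshold with DESeq2 (4.48), limma voom (4.52), sample quality weights (5.91), surrogate variables (4.78), FPKM with offsets of 0.1 and 1 (4.47 and 4.41) and with a mean FPKM of at least 1 (4.41). It also passed with the set term (4.63), the set term with weights (5.93), replicates 1 to 3 alone (6.32), the set term without replicates 7 to 9 (5.27) and the block with weights (5.72). DESeq2 with the set term gave 4.54 and no p-value, so it was not called, and in edgeR with the set term it did not pass without replicates 1 to 3 (3.80) or 4 to 6 (4.90). Leaving out replicates moved it between 4.03 (without replicate 7) and 5.56 (without replicate 9).

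With the replicate number as a block, Aqp2 was 4.70 (edgeR adjusted p = 0.124) and 1 gene was called, Cited1. By camera the ribosomal protein genes stayed the only list called with the block. By fry for change in either direction, principal cell genes gained a call (fry adjusted p = 0.00429, against 0.223 without the block). Only Aqp2 passed over that list alone, so this call may rest on Aqp2. Directional fry (adjusted p = 0.186) and camera (adjusted p = 0.163) did not call the list with the block. Adjusted over the list alone, Atf3 and Jun fell among cAMP and CREB targets with the block.

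The count of 0 genes became 6 with DESeq2, 1 with limma voom, 11 with weights, 1 with the block, 7 with surrogate variables and 2 with each use of FPKM. It became 8 with the set term, 118 with the set term and weights (82 at least 2-fold), 40 with the set term in DESeq2 (38 at least 2-fold), 41 in replicates 1 to 3, 8 with the set term without replicates 7 to 9, and 95 with the block and weights (82 at least 2-fold). Leaving out libraries gave 0 to 1, the 1 being Aqp2 without control 9 or replicate 9. Other normalizations, filters, robust fitting and the log10 total kept 0.

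The count of 8 with the set term became 40 with DESeq2 and 118 with weights, and lay between 4 (without dDAVP 8) and 9 (without control 8 or dDAVP 6). The count of 11 with weights became 36 without control 9 and dDAVP 6 together and 118 with the set term, and lay between 1 (without dDAVP 2 or dDAVP 3) and 33 (without control 4). The count of genes changed in replicates 1-3 (41) became 113 with DESeq2, 207 without a filter and 101 with the block, and lay between 13 (without control 2) and 774 (without dDAVP 1).

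The 1 list called became 0 with an estimated correlation and by fry, directional or mixed, 2 with the set term and 4 in replicates 1 to 3. It became 0 without replicate 1 or 4 and at most 3 without replicate 8 or 9. With the set term, directional fry called 0 lists. Fry for change in either direction called 1 there, principal cell genes (fry adjusted p = 9.76e-07). Of the 17 members tested only Aqp2 passed over the list alone, so this call may rest on Aqp2. For the same list directional fry (adjusted p = 0.214) and camera (adjusted p = 0.258) made no call.

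Against TMM, library totals only moved the median of all genes by 0.20 (log2), and with them Scnn1a (0.54), Fras1 (0.22) and Cpe (0.24) turned positive. Scnn1g turned positive with RLE size factors (0.054), DESeq2 (0.075), limma voom (0.99), the block (0.50), surrogate variables (0.078), the log10 total (0.20), the set term (0.67), the set term in DESeq2 (0.77), replicates 7 to 9 (4.19) and the set term without replicates 1 to 3 (1.83). Fras1 turned positive with log2(FPKM + 1) (0.0063), in replicates 7 to 9 (1.80) and with the set term without replicates 1 to 3 (0.82) or 4 to 6 (0.049). In replicates 7 to 9 Scnn1a was 0.20, Cpe 0.42, Sprr2g -0.044, Spink8 -1.61 and Arl4d -0.031; in replicates 4 to 6 Avpr2 was -0.27 and Car15 -0.022; in replicates 1 to 3 Scnn1b was 0.87. Leaving out replicates moved Avpr2 between -0.045 and 0.39, Fras1 between -0.89 and 0.12, Scnn1a between -0.47 and 0.27 and Scnn1g between -1.11 and 0.69. Aqp5 moved between 1.05 and 2.94 (without replicate 8). Aqp3 and Aqp4 fell below the filter and have no fold here.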

Other observations

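The tests of the fit without covariates against other splits were chosen after its result was seen. Atf3, a stress-response transcription factor, averaged 13.5 ± 8.78 CPM in control and 5.97 ± 5.53 CPM with dDAVP (SD, n = 9) and was higher with dDAVP in 0 of 9 replicate numbers; with the set term its log2 fold change was -1.51 (SE 0.38), not called by edgeR (adjusted p = 0.308). With the set term it was called by DESeq2 (-1.53, adjusted p = 0.00391) and by weighted limma voom (-1.61, adjusted p = 0.0114). Arg2, the mitochondrial arginase, averaged 0.718 ± 0.602 CPM in control and 10.2 ± 13.1 CPM with dDAVP and was higher in 8 of 9 numbers, with a log2 fold change of 2.98 (SE 0.82) in the fit with the set term, also not called by edgeR (adjusted p = 0.465). With the set term it was called by DESeq2 (2.92, adjusted p = 0.022) and by weighted limma voom (4.01, adjusted p = 9.06e-08). Car15 and Aqp5 were each higher with dDAVP in 7 of 9 numbers.

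Other splits of the 18 libraries into groups of 9 were counted for edgeR without covariates, with the set term and with the replicate block, and for limma voom with sample quality weights. No splits were counted for the other fits of all 18 libraries. For the fit without covariates, 100 of 100 splits gave at least the real 0 genes, as any split must, so this count says nothing about chance. The highest other gave 2478, from a side of control 4, 5, 6, 8 and 9 with dDAVP 4, 6, 7 and 8, which follows the sets and points to a structure of the samples. With sample quality weights 64 of 100 splits gave at least the real 11 (highest other 6827, the same structure), so chance is not excluded over all splits. Among splits within sets it was 1 of 100 (highest other 9). Among splits that part every pair of numbers it was 2 of 60 (highest other 11). With the set term, chosen after seeing the data, 1 of 100 splits within sets, the real one, gave 8 genes (highest other 0). Of splits that part every pair, 1 of 60 did so (highest other 1). With the replicate block it was 1 of 60 for the real 1 gene (highest other 0). These shares argue against chance among such splits but do not exclude it, since they are not adjusted over the split tests. Without covariates 60 of 60 splits that part every pair gave at least 0 (highest other 0), as any split must, which says nothing about chance either.

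Within sets there are 10 splits, too few to exclude chance. Replicates 1 to 3 gave 41 genes in 1 of 10 (highest other 19), replicates 4 to 6 gave 0, which all 10 of 10 must reach (highest other 0), and replicates 7 to 9 also gave 0, again 10 of 10 (highest other 1050, the division across the labels). For gene lists, 72 of 100 splits gave at least the real 1 list without covariates (highest other 8) and 30 of 100 at least the real 2 with the set term (highest other 8), so chance is not excluded; in replicates 1 to 3 it was 3 of 10 for the real 4 (highest other 7), too few to exclude chance.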
